A study of Mus musculus with 16 samples.

How the data were processed

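Expression was measured in total lung RNA of female BALB/c mice, in 16 samples forming 4 groups of 4, on 1-colour Affymetrix whole-genome mouse arrays. Groups were taken from the labels' source name and gestation fields. For non-pregnant PBS replicate 2 these fields conflict, since one calls the mouse pregnant and another non-pregnant; it was placed in the non-pregnant group because the design text gives 4 samples per group. Replicate numbers are only the order of the samples. The labels give 4 separate samples in each group; whether each comes from 1 mouse is not stated, and each array was treated as 1 mouse.

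The deposited table holds 1 linear intensity per probe set and array, for 45101 probe sets. Per the submitters' processing notes, GCOS, MAS5 and RMA were used; their versions, their order and which of them made the deposited values are not given in the sources used here. The values themselves are linear and not scaled between arrays: the trimmed mean signal (2% left out at each end) ran from 137 to 264, a ratio of 1.92, and the median signal from 32.0 to 56.6. Because the deposited intensity values differ in brightness, quantile normalization between arrays was made the setting for all reported values. That normalization had first been listed as the alternative to the values as deposited; the roles were exchanged once the table had been seen, and the values as deposited became the alternative.

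From the deposited intensities, the 64 control probe sets were left out, the rest were quantile-normalized on the linear scale, and log2(value + 16) was taken. All changes are differences on that scale, which understates the change of weak signals. A probe set was kept when its value was above its array's median on at least 4 of the 16 arrays, which left 23995. Probe sets were named through the platform annotation, with symbols brought up to date by Entrez identifier against a RefSeq gene table of GRCm38.p6, used for names only: 34958 had 1 gene symbol, 932 several and 9160 none listed, and 34754 of the first matched the table. Of the kept probe sets 21248 had a single symbol. The one with the highest mean over all arrays stood for each gene, giving 12369 genes, and 2747 kept probe sets without a single symbol were counted apart.

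Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in one fit of 4 group means over the 16 arrays with 12 residual degrees of freedom. The 5 contrasts were TiO2 minus PBS in non-pregnant mice, the same in pregnant mice, the difference of these (interaction), and pregnant minus non-pregnant after PBS and after TiO2. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. Errors of log2 changes are standard errors of the fit (SE), and group values are means with standard deviations (SD). Beside this, 34 lists of cell type markers and pathway genes (774 entries, 706 with a named probe set) were tested with limma's camera, two-sided, at a preset correlation between genes of 0.01. Lists needed at least 5 measured genes; 33 had them, and the list of mast cell, basophil and eosinophil genes did not. Camera was repeated with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance one way, was run as well. For every called list the median, the mean and the test had the same sign. Means per array of the cytokine and neutrophil lists were compared by two-sided exact permutation tests over 70 assignments, whose smallest possible p is 0.0286. These 4 tests form one family for the adjusted values.

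The tests, the gene lists, the thresholds, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per contrast, up to 8 called genes with the largest rise and up to 8 with the largest fall whose groups do not overlap. Where fewer passed, the genes with the smallest p were added up to 4 per direction. It also named up to 3 members of each called list, 16 inflammation and metal-response genes in both TiO2 contrasts, and Xist and Ddx3y. Ddx3y has no named probe set here. Of the list members so picked, only examples are printed. Several steps were added after the data had been seen: scaling to a common trimmed mean, fits without arrays of unlike tissue content, tissue list means or Glycam1 as covariates, the squamous, muscle, thymic epithelium and haemoglobin marker lists, and values of preset genes below the filter. Other alternatives covered the filter, the pseudocount (1 and 64), the arrays in the fit, the spread estimate, array weights, the probe set per gene and each array left out.

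The procedure was tested on simulated data with the real means and spreads, with 50 genes changed at each size among 12369. For changes of 1.5, 2, 3 and 4 times it recovered 72%, 88%, 100% and 98% for TiO2 in non-pregnant mice and 82%, 94%, 98% and 100% in pregnant mice. The shares were 36%, 84%, 96% and 96% for the interaction, 70%, 94%, 96% and 96% for pregnancy after PBS, and 60%, 92%, 100% and 100% for pregnancy after TiO2. Changes of all sizes were planted together, which eases the adjusted threshold, so recovery would be lower where few genes change. A comparison without calls can therefore still hold single genes changed by more than 2 times. False calls made up 3.76%, 6.97%, 1.89%, 5.82% and 2.22% of the calls in that order, and with no list shifted 0 of 33 lists were called by camera. The simulated genes vary independently, which real ones do not: splits of the real arrays that mix the groups gave a median of 6, 7, 6, 8 and 6.5 lists called in the same order. The number of arrays limits the precision: the median SE was 0.12 log2 for a comparison of 2 groups and 0.17 for the interaction. The design text also mentions diesel exhaust particles and a later time point, which were not analysed here.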

Results

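Lung expression was compared between pregnant and non-pregnant BALB/c mice, an inbred laboratory strain, after titanium dioxide (TiO2) particles or saline. Mice received 50 ug of TiO2, a dust commonly treated as inert and here baked free of endotoxin, or the phosphate-buffered saline vehicle (PBS) into the nose, and lung RNA was taken 19 hours later. Pregnant mice were at gestation day 14. The labels give 4 separate samples in each of the 4 groups, with 1 array each, and 12369 genes passed the expression filter. The study's stated question was whether pregnancy changes the slight inflammation that such particles normally cause.

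Arrays of one group correlated with r between 0.939 and 0.991 (median 0.983), and arrays of different groups between 0.936 and 0.988 (median 0.977). Xist, which is expressed from the inactive X chromosome of females, was at 10.9 to 12.0 log2 on all 16 arrays. The 18S ribosomal RNA signal averaged 183 ± 59.6 in non-pregnant mice after PBS, 430 ± 207 after TiO2, 85.0 ± 14.8 in pregnant mice after PBS and 143 ± 78.8 after TiO2 (SD, n = 4 each). Labels gave RNA at 0.458 to 0.833 ug per uL, and beta-actin threshold cycles of 12.5 to 15.6. Non-pregnant PBS replicate 2, whose labels conflict, was nearer to the other 3 non-pregnant PBS arrays than to pregnant PBS in 90 of the 116 genes called for pregnancy without it.

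Transcripts typical of thymus, squamous epithelium, striated muscle, lymph node venules and fat differed between arrays. Prss16, a protease of the thymic epithelium, was at 8.98 and 9.72 log2 in non-pregnant PBS replicates 3 and 4 and at most 6.32 on the other 14 arrays. The thymocyte list mean was 8.18 and 8.38 in these 2 against 6.09 to 6.89 elsewhere. Pregnant TiO2 replicate 2 lacked squamous keratins and fast striated muscle genes that the other 15 arrays had: Krt13 was 5.21 against at least 10.7, and the muscle actin Acta1 6.56 against at least 11.9. Glycam1, a mucin of lymph node venules, was at 4.14 and 4.60 in non-pregnant TiO2 replicates 1 and 4 and at 4.15 in pregnant TiO2 replicate 2, and between 8.06 and 10.8 on the other 13 arrays. Fat markers also varied, with Adipoq, the hormone adiponectin, between 7.73 and 11.5 log2 over the 16 arrays.

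**Figure D1:**
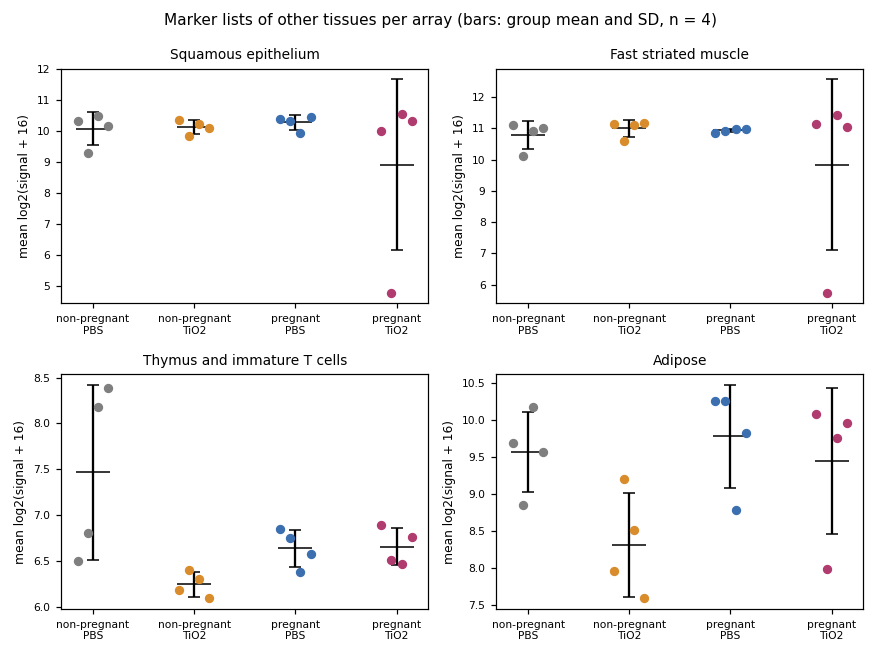
Mean log2(signal + 16) of marker lists of squamous epithelium, fast striated muscle, thymus and fat, 1 point per array, with group mean and SD (n = 4). Pregnant TiO2 replicate 2 lies at 4.78 for the squamous list where the other arrays lie between 9.28 and 10.5, and 2 non-pregnant PBS arrays lie at 8.18 and 8.38 for the thymus list.

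In non-pregnant mice, camera at the preset correlation called lymphocyte and fat lists lower after TiO2, but none kept its call with an estimated correlation. All 18 measured T-cell genes lay lower (list median −0.89 log2), as did 17 of 18 B and plasma cell genes (median −0.59), 8 of 9 natural killer cell genes (median −0.34) and all 12 fat markers (median −1.46). Camera's adjusted p was 4.56e-09, 3.01e-08, 0.00284 and 8.95e-07 for these lists, and the adjusted p = 0.407, 0.248, 0.469 and 0.407 with an estimated correlation. Examples are Cd3d, a chain of the T-cell receptor complex (−1.34 ± 0.39), the B-cell complement receptor Cr2 (−0.75 ± 0.22), the transcription factor Eomes (−0.73 ± 0.19) and the fat cell lipid carrier Fabp4 (−1.63 ± 0.50; log2 ± SE, n = 4 against 4). Glycam1 moved with them, at 8.91 to 10.6 after PBS and at 4.14, 9.29, 8.06 and 4.60 in TiO2 replicates 1 to 4; with it as a covariate the fat median was −0.25 (adjusted p = 0.0590) and the B-cell median −0.45 (adjusted p = 7.00e-06). The thymocyte list moved with them (median −1.02, adjusted p = 1.82e-05, and adjusted p = 0.170 with an estimated correlation). Adjusted over the list alone, 10 T-cell, 11 B-cell, 1 natural killer, 7 fat and 5 thymocyte genes were called lower, and 0 of them over all genes. Without the 2 arrays with thymus transcripts the T-cell median was −0.01 (adjusted p = 0.713), while the B-cell, natural killer and fat medians were −0.45 (adjusted p = 0.000148), −0.22 (0.0325) and −0.92 (0.00388). These adjusted p are camera's at the preset correlation. With an estimated correlation, and without pregnant TiO2 replicate 2 as well, the B-cell, natural killer and fat lists each had adjusted p = 0.898.

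Among other lists, the glucocorticoid-response genes lay higher after TiO2 in these mice (17 of 19 members, median 0.33, adjusted p = 4.00e-07). With an estimated correlation the adjusted p = 0.407. Without the 2 thymus arrays the median of this list was 0.21 (adjusted p = 0.0132 at the preset correlation). Its members include the kinase Sgk1 (0.24 ± 0.11) and the transcription factor Klf9 (0.26 ± 0.08). The cell-cycle list was called lower (27 of 28 members below 0, median −0.37, adjusted p = 1.53e-07), but its adjusted p = 0.495 with an estimated correlation and its median was 0.04 (adjusted p = 0.413) without those arrays. Its member Mcm2, a subunit of the replicative helicase, was at −0.49 ± 0.10. Acute-phase genes were called higher (median 0.18, adjusted p = 0.0118, and adjusted p = 0.407 with an estimated correlation). This list's median was 0.05 (adjusted p = 0.903) without the 2 arrays. Lcn2, which binds bacterial siderophores, stood at 0.66 ± 0.19, and Pigr, the carrier of IgA across epithelium, at 0.43 ± 0.14. Heat-shock genes (median 0.07, adjusted p = 0.000577), endothelial markers (0.06, 0.0118) and club cell genes (0.09, 0.0118) were also called higher, and cholesterol synthesis genes (−0.07, 0.0161) and striated muscle genes (−0.17, 0.000856) lower, though these 2 medians were 0.13 and 0.02 with values as deposited, where all genes rose by a median of 0.17. None of these 5 calls held with an estimated correlation (adjusted p = 0.248, 0.495, 0.495, 0.519 and 0.627), only the muscle call held without the 2 arrays, and the club cell median turned to −0.05 with trimmed-mean scaling. With Glycam1 as a covariate the muscle median was 0.01 (camera's adjusted p = 0.552). The endothelial and cholesterol calls were also lost there (0.365 for both), while the heat-shock and club cell calls held (0.00195 and 0.00116). Examples are the chaperone Dnajb1 (0.47 ± 0.15), Tff2 (0.70 ± 0.17), the desaturase Scd1 (−0.69 ± 0.13) and the troponin Tnnt2 (−0.52 ± 0.10).

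No gene changed in non-pregnant mice at the threshold: limma called 0 of 12369, with 1223 at an unadjusted p under 0.05 where chance gives 618, and the lowest adjusted p was 0.146. The genes with the smallest p, none of which passed, were Tmem252 (0.98 ± 0.19), Ercc5 (0.39 ± 0.07), Mcf2l (0.55 ± 0.12) and Plekha8 (0.44 ± 0.09) on the higher side, and Sbk1 (−0.53 ± 0.10) and Adap1 (−0.63 ± 0.12) beside Scd1 and Tnnt2 on the lower. In each of these 8 the groups did not overlap, which held for 5.20% of all genes against 2.86% by chance. The chance numbers given here and below are averages. Genes move together, so a surplus over such an average does not by itself show an effect. Leaving out non-pregnant PBS replicate 1 gave 5 calls (Ccnd3, Dnajc6, Il1a, Prkcb and St8sia1), replicate 2 gave 5 (Apoc1, Lmcd1, Nfatc3, Plekha8 and Sbk1) and non-pregnant TiO2 replicate 3 gave 1 (Rhbdd3), all named after their values were seen. Lists called numbered 13 of 33, and 7 without non-pregnant PBS replicate 3.

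None of the preset inflammation genes passed the threshold in non-pregnant mice. The neutrophil chemokine Cxcl1 was at 0.06 ± 0.25 log2, the cytokine Il1b at −0.39 ± 0.14, the neutrophil calcium-binding proteins S100a8 and S100a9 at −0.30 ± 0.21 and −0.41 ± 0.21, the serum amyloid Saa3 at 0.59 ± 0.32 and Lcn2 at 0.66 ± 0.19, with adjusted p between 0.303 and 0.962. Haem oxygenase Hmox1 was at 0.02 ± 0.17, and the metallothioneins Mt1 and Mt2 at −0.02 ± 0.15 and 0.23 ± 0.23. The macrophage scavenger receptor Marco was at −0.80 ± 0.38 (adjusted p = 0.504). Marco was near the floor after TiO2 and also in PBS replicates 2 and 4 (4.23 and 4.16). Its difference rests on PBS replicates 1 and 3 (6.55 and 5.54), so its size is uncertain. Cxcl2, Cxcl5, Ccl2, Ccl3, Il6 and Tnf were below the expression filter, at 4.04 to 6.21 log2 on all arrays, and none passed in a fit without the filter. There Cxcl2 was at 0.32 in non-pregnant mice (adjusted p = 0.662) and at 0.64 in pregnant mice (adjusted p = 0.675). The mean of the 17 cytokine and chemokine genes per array was 7.64 ± 0.06 after PBS and 7.62 ± 0.05 after TiO2 (SD, n = 4), a difference of −0.03 within the spread (exact permutation p = 0.514, adjusted 0.514). That of the 19 neutrophil markers was 7.89 ± 0.12 and 7.76 ± 0.12, a difference of −0.13 (exact permutation p = 0.171, adjusted 0.229).

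In pregnant mice, camera at the preset correlation called neutrophil markers lower after TiO2 and acute-phase, complement and matrix genes higher; none of these lists kept its call with an estimated correlation (adjusted p = 0.124, 0.256, 0.124 and 0.424). Of the 19 neutrophil markers 14 lay lower (median −0.33, camera's adjusted p = 2.60e-07, and adjusted p = 0.124 with an estimated correlation). S100a8 was at −1.13 ± 0.21 log2, S100a9 at −1.06 ± 0.21 and the myeloid receptor Trem3 at −0.56 ± 0.10, with adjusted p of 0.257, 0.267 and 0.257. S100a8 averaged 12.37 ± 0.29 after PBS and 11.24 ± 0.23 after TiO2 (SD, n = 4), with no overlap between the groups. Adjusted over the list alone, 9 markers were called lower and 1 higher, and 0 over all genes. Their mean per array was 8.65 ± 0.16 after PBS and 8.25 ± 0.14 after TiO2, lower by 0.41 (exact permutation p = 0.0286, the smallest this design allows, adjusted 0.114). Without pregnant TiO2 replicate 1 or 2 the difference was −0.36 or −0.37, both with exact p = 0.0571, and it was −0.28 (exact p = 0.143) with the conflicting array counted as pregnant PBS.

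Acute-phase genes lay higher in these mice in 11 of 14 members (median 0.20, adjusted p = 0.000373, and adjusted p = 0.256 with an estimated correlation). Saa3 stood at 1.19 ± 0.32, Lcn2 at 0.77 ± 0.19 and Pigr at 0.69 ± 0.14; for each the groups did not overlap, and the adjusted p was 0.513, 0.447 and 0.267. Complement and coagulation genes had a median of 0.20 (14 of 21 higher, adjusted p = 0.000373, and adjusted p = 0.124 with an estimated correlation), with the complement component C1qa at 0.40 ± 0.09 and the protein C receptor Procr at 0.32 ± 0.07. Adjusted over the list alone, 4 acute-phase and 4 complement genes were called higher and 1 of each lower. Matrix genes had a median of 0.17 (19 of 26 higher, adjusted p = 0.000359, and adjusted p = 0.424 with an estimated correlation), among them the protease inhibitor Timp1 (0.47 ± 0.14), the stromelysin Mmp3 (0.44 ± 0.14) and the fibril protein Mfap5 (0.42 ± 0.09), all 3 called over the list alone. Cell-cycle genes lay higher in 27 of 28 members, none of them called (median 0.32, adjusted p = 8.11e-08, and adjusted p = 0.452 with an estimated correlation), with Birc5 at 0.72 ± 0.25 and Cdk1 at 0.68 ± 0.27. Ciliated cell genes (median 0.13, adjusted p = 0.00389), smooth muscle and fibroblast genes (0.14, 0.0253) and alveolar type 1 genes (0.06, 0.0453; −0.01 with values as deposited, where all genes fell by a median of 0.08) were called higher, and striated muscle genes lower (−0.27, 0.000329). Their adjusted p = 0.452, 0.424, 0.424 and 0.723 with an estimated correlation. The muscle list moves with pregnant TiO2 replicate 2, and its median was 0.07 (adjusted p = 0.413) and that of the alveolar type 1 list 0.00 (adjusted p = 0.335) without the 3 arrays of unlike tissue content. The hormone precursor Nppa of heart muscle was at −1.49 ± 0.37.

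Over all genes limma called 0 of 12369 in pregnant mice, with 795 at an unadjusted p under 0.05 and a lowest adjusted p of 0.257. The genes with the smallest p, none passing, were Pigr, Mmp12 (0.55 ± 0.11), Szrd1 (0.47 ± 0.10) and Mfap5 on the higher side and S100a8, Trem3, Klra17 (−0.80 ± 0.14) and Armcx4 (−0.45 ± 0.09) on the lower. Il1b was at −0.62 ± 0.14 (adjusted p = 0.373), and Cxcl1, Hmox1, Mt1, Mt2 and Marco at 0.13 ± 0.25, −0.06 ± 0.17, −0.00 ± 0.15, 0.12 ± 0.23 and 0.01 ± 0.38. Leaving out non-pregnant PBS replicate 3 gave 1 call (Trem3), and leaving out pregnant TiO2 replicate 3 gave 1 (Klra17, adjusted p = 0.0351). The cytokine and chemokine mean was 7.84 ± 0.06 after PBS and 7.91 ± 0.04 after TiO2, a difference of 0.07 (exact permutation p = 0.114, adjusted 0.229). Without the expression filter this difference was 0.11 (exact p = 0.0286).

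**Figure D2:**
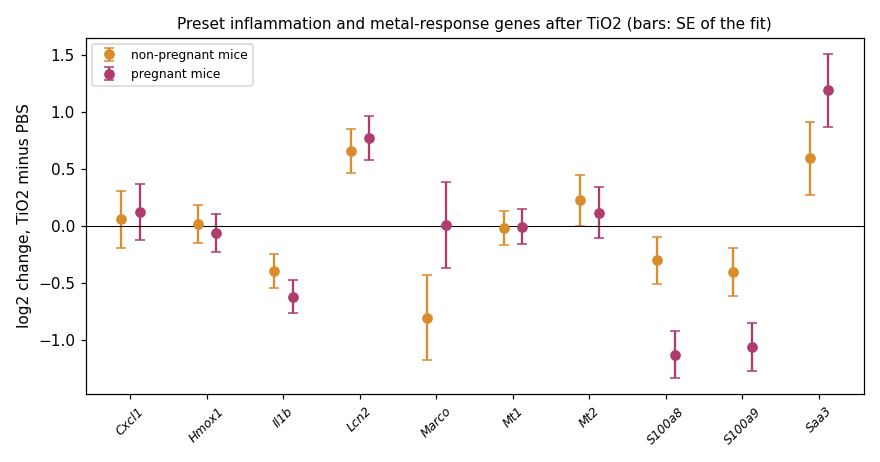
Log2 change after TiO2 minus PBS (log2 of signal + 16) of 10 preset inflammation and metal-response genes in non-pregnant and pregnant mice, with SE of the fit (n = 4 per group). None passed the threshold; S100a8 and S100a9 lie at −1.13 and −1.06 in pregnant mice, and Saa3 at 1.19.

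The direct test of the study's question is whether the response to TiO2 differed with pregnancy. Cell-cycle genes differed as a list: their median response was 0.72 log2 more positive in pregnant mice, with all 28 members on that side (adjusted p = 4.74e-12, and adjusted p = 0.650 with an estimated correlation). T-cell (0.90), thymocyte (0.98), fat (1.06) and B and plasma cell genes (0.44) were also more positive, with adjusted p of 1.94e-05, 0.00395, 0.0234 and 0.000541. Neutrophil markers (−0.20, 0.0234), glucocorticoid-response genes (−0.30, 0.00403) and heat-shock genes (−0.11, 0.0234) were more negative. With an estimated correlation the adjusted p = 0.650 to 0.780 for all 8 lists. Examples are Birc5 (1.42 ± 0.35), the T-cell surface protein Thy1 (1.55 ± 0.53), the antibody joining chain Jchain (0.96 ± 0.30), the neutrophil collagenase Mmp8 (−1.28 ± 0.43) and S100a8 (−0.83 ± 0.29). Without the 2 thymus arrays the cell-cycle difference was 0.27 (adjusted p = 0.000316) and the B-cell one 0.35 (adjusted p = 0.0107). Those of T cells, fat, glucocorticoid, heat-shock and neutrophil genes, 0.14, 0.61, −0.18, −0.07 and −0.22, no longer passed (adjusted p = 0.615, 0.166, 0.144, 0.333 and 0.144). These adjusted p are camera's at the preset correlation. With an estimated correlation, and without pregnant TiO2 replicate 2 as well, the cell-cycle and B-cell lists each had adjusted p = 0.778. With Glycam1 as a covariate on all arrays the fat difference was 0.37 (camera's adjusted p = 0.107), while the other lists kept their calls at the preset correlation.

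Single genes gave no call for this difference: limma called 0 of 12369, with 1352 at an unadjusted p under 0.05 and a lowest adjusted p of 0.232. Adjusted over the list alone, 3 cell-cycle genes were called higher and 0 genes of the other 7 lists. The genes with the smallest p, none passing, were Dipk1b (0.78 ± 0.14), Adap1 (0.84 ± 0.17), Pmf1 (1.22 ± 0.24) and Dctn6 (1.13 ± 0.23) on the positive side and Cnksr3 (−0.64 ± 0.13), Gdpd1 (−0.70 ± 0.14), Tfdp2 (−0.81 ± 0.16) and Jade2 (−0.71 ± 0.15) on the negative. Leaving out non-pregnant PBS replicate 2 gave 2 calls, Nfatc3 and Plekha8. Across genes the TiO2 effects in the 2 kinds of mice correlated with Pearson's r of −0.09 and Spearman's rho of −0.17; genes are not independent replicates, so no p is given.

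Pregnancy itself separated the mice most clearly. After PBS, neutrophil and platelet genes rose in pregnant lungs: 9 of 19 neutrophil markers passed over all genes and 15 adjusted over the list alone (median 0.71), and 6 of 12 platelet genes, or 10 over the list alone (median 0.74), all higher. S100a9 rose 3.11-fold (1.64 ± 0.21, adjusted p = 0.00143), S100a8 2.75-fold (1.46 ± 0.21), Mmp8 3.14-fold (1.65 ± 0.30) and the platelet chemokine Ppbp 2.70-fold (1.43 ± 0.22). Il1b went from 7.82 ± 0.31 to 9.20 ± 0.22 (SD, n = 4; adjusted p = 0.000762). Camera's adjusted p was 8.68e-20 for neutrophil and 1.59e-16 for platelet genes and stayed under the threshold with an estimated correlation (adjusted p = 0.00290 and 0.0215). Without the 3 arrays of unlike tissue content the platelet call was lost there (adjusted p = 0.182 with an estimated correlation), and the neutrophil call was not (0.0419). Macrophage markers (median 0.17, adjusted p = 6.65e-06, and adjusted p = 0.00638 with an estimated correlation) made up the third list of which this was true, with Cd68 at 0.60 ± 0.11 and the chitinase-like protein Chil3 at 0.87 ± 0.13. Of its 23 members 2 passed over all genes and 3 adjusted over the list alone. Erythroid genes moved with them (median 0.23, adjusted p = 0.0212, and adjusted p = 0.248 with an estimated correlation), 0 of 11 passing over all genes, and Slc4a1, the red cell anion exchanger, was at 0.75 ± 0.21 (adjusted p = 0.123).

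Limma called 129 of 12369 genes for pregnancy after PBS, 100 higher and 29 lower, 22 of them by more than 2-fold; in 127 of these the groups did not overlap. Over all genes, called or not, this held for 5.76%, against 2.86% by chance. Other rises were those of Oas3 (1.92 ± 0.44), an antiviral synthetase, Slfn4 (1.75 ± 0.31), Apol11b (1.52 ± 0.33) and Clec4e (1.51 ± 0.18), a receptor for mycobacterial glycolipid. In non-pregnant mice Oas3, Apol11b and Clec4e averaged 5.13, 4.48 and 5.77, below the median of all probe sets of 5.94, so their changes are lower bounds. Falls were led by the chemokine Cxcl14 (−0.98 ± 0.15), Cntn4 (−0.86 ± 0.10), the microfibril protein Mfap4 (−0.83 ± 0.19), Pmf1 (−0.74 ± 0.17), Fbxo5 (−0.69 ± 0.14), Sncb (−0.68 ± 0.13), Tfpi2 (−0.64 ± 0.13) and the amino acid transporter Slc38a5 (−0.63 ± 0.11). The count was 72, 78 and 217 without pregnant PBS replicate 1, pregnant PBS replicate 2 and non-pregnant PBS replicate 3. It was 245 without the 2 thymus arrays, with 90 of the 129 among them. With the 3 tissue list means as covariates it was 132, with 60 of the 129 among them. It was 38 with values as deposited, all higher, and 7 with the conflicting array counted as pregnant PBS.

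Other lists also shifted with pregnancy after PBS. Immediate-early genes lay higher (median 0.42, adjusted p = 3.66e-06, and adjusted p = 0.0957 with an estimated correlation), led by the nuclear receptor Nr4a1 (1.33 ± 0.17, adjusted p = 0.00143); 1 of 16 passed over all genes, and adjusted over the list alone 9 were higher and 1 lower. B and plasma cell genes lay higher in 18 of 18 members (median 0.30, adjusted p = 6.50e-06, and adjusted p = 0.160 with an estimated correlation), of which the IgA heavy chain Igha alone passed over all genes (1.27 ± 0.23) and 3 adjusted over the list alone. Matrix genes lay lower in 22 of 26 members (median −0.20, adjusted p = 6.35e-07, and adjusted p = 0.123 with an estimated correlation), with Mfap4 and Mfap5 (−0.58 ± 0.09) called over all genes and 5 adjusted over the list alone. Heat-shock genes (−0.12) and smooth muscle and fibroblast genes (−0.09) were called lower with adjusted p of 0.01 and 0.0493, and adjusted p = 0.228 and 0.362 with an estimated correlation. With values as deposited, where all genes rose by a median of 0.16, these medians were 0.03 and 0.06. Cytokines (0.13), alternative activation genes (0.21), interferon-response genes (0.10) and NF-kB targets (0.07) were called higher with adjusted p of 0.00914, 0.00592, 0.0436 and 0.0390, and adjusted p = 0.0957, 0.0533, 0.577 and 0.254 with an estimated correlation. So were acute-phase (0.31, 0.000780), ciliated cell (0.12, 0.01) and club cell genes (0.13, 0.00592), with adjusted p = 0.130, 0.362 and 0.332 with an estimated correlation. Called members include the growth factor Csf1 (0.49 ± 0.09), the antiviral Rsad2 (0.92 ± 0.21) and Oas2 (0.83 ± 0.18), Ier3 (0.56 ± 0.11) and Npnt (−0.41 ± 0.08). Cell-cycle (−0.44), T-cell (−0.44) and thymocyte genes (−0.78) were called lower (adjusted p = 8.35e-11, 0.00592 and 0.00592, and adjusted p = 0.248, 0.577 and 0.157 with an estimated correlation). Without the 2 thymus arrays the cell-cycle median was −0.01 (adjusted p = 0.734) and the T-cell median turned to 0.30 (adjusted p = 0.000598). The acute-phase, cytokine, NF-kB, erythroid, ciliated and club cell calls were also lost (adjusted p = 0.283, 0.113, 0.0875, 0.557, 0.281 and 0.800). These adjusted p without the 2 arrays are camera's at the preset correlation. With an estimated correlation, and without pregnant TiO2 replicate 2 as well, the T-cell list had adjusted p = 0.299.

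After TiO2, antibody genes were higher in pregnant than in non-pregnant lungs. All 18 B and plasma cell genes lay higher in pregnant mice (median 0.91, adjusted p = 1.92e-12, and adjusted p = 0.0351 with an estimated correlation), 6 passing over all genes and 16 adjusted over the list alone. Without the 3 arrays of unlike tissue content the call was lost (adjusted p = 0.0748 with an estimated correlation). Jchain rose 3.22-fold (1.69 ± 0.21, adjusted p = 0.00331), Igha 3.17-fold (1.67 ± 0.23) and the plasma cell chaperone Mzb1 2.00-fold (1.00 ± 0.13), as did the kappa variable segments Igkv8-30 (2.08 ± 0.35), Igkv9-120 (1.61 ± 0.27) and a further segment of family 15 (1.53 ± 0.27, a lower bound from a weak 5.36), which resemble one another in sequence. Fat markers moved with them (12 of 12 higher, median 1.33, adjusted p = 0.000284, and adjusted p = 0.444 with an estimated correlation), 0 passing over all genes and 5 adjusted over the list alone. So did Glycam1, at 10.6 to 10.8 in 3 pregnant TiO2 arrays and 4.15 in replicate 2, against 4.14 to 9.29 in non-pregnant ones. With Glycam1 as a covariate the B-cell median was 0.74 (adjusted p = 5.95e-12) and the fat median 0.25 (adjusted p = 0.0632). With thymus, fat and squamous list means as covariates the B-cell median was 0.17 (adjusted p = 0.00121).

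Neutrophil markers were again higher in pregnant mice (median 0.46, 7 of 19 called and 12 over the list alone, adjusted p = 1.12e-07, and adjusted p = 0.0351 with an estimated correlation). S100a9 was at 0.98 ± 0.21, Lrg1 at 1.17 ± 0.16, the peptidoglycan-binding Pglyrp1 at 1.16 ± 0.16 and, from the cytokine list, Il1b at 1.15 ± 0.14, all called. Platelet genes had a median of 0.60 (5 of 12 called and 11 over the list alone, adjusted p = 1.10e-08, and adjusted p = 0.0709 with an estimated correlation), with Clec1b at 1.09 ± 0.13 and Ppbp at 1.05 ± 0.22. Macrophage markers (0.28, adjusted p = 3.49e-06) and cytokines (0.23, adjusted p = 0.000414) kept their calls with an estimated correlation (adjusted p = 0.00921 and 0.0351); 4 of 23 and 1 of 17 passed, or 12 and 8 over the list alone. Without the 3 arrays only macrophage markers kept it (adjusted p = 0.0303 with an estimated correlation); neutrophil markers, cytokines and heat-shock genes had 0.0599, 0.105 and 0.0748. Marco rose from 4.32 ± 0.30, at the floor that the added 16 sets, to 6.19 ± 0.15, so that its 1.87 ± 0.38 is a lower bound, and the complement subunits C1qa and C1qc rose by 0.48 ± 0.09 and 0.51 ± 0.09. Heat-shock genes lay lower in 19 of 21 members (median −0.17, adjusted p = 1.48e-06, and adjusted p = 0.0351 with an estimated correlation), with the chaperones Hsph1 (−0.82 ± 0.17), Dnaja1 (−0.53 ± 0.11) and Hspa8 (−0.30 ± 0.07) called over all genes and 6 over the list alone. Only 2 of the 4 probe sets of Hspa8 fell.

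**Figure D3:**
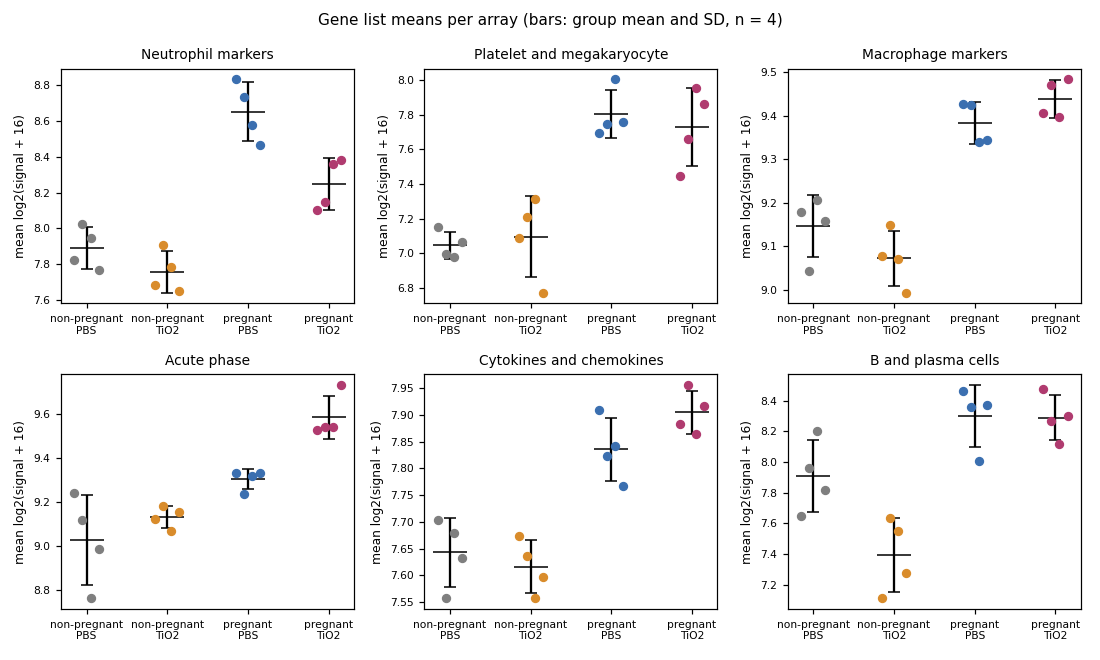
Mean log2(signal + 16) of 6 gene lists, 1 point per array, with group mean and SD (n = 4). In pregnant mice the neutrophil list averaged 8.65 after PBS and 8.25 after TiO2, and in non-pregnant mice 7.89 and 7.76.

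Limma called 233 genes for pregnancy after TiO2, 170 higher and 63 lower, 25 by more than 2-fold, and in 228 the groups did not overlap. Over all genes, called or not, the groups did not overlap in 15.7%, against 2.86% by chance. Beside the genes above, rises were led by the acute-phase protein Orm1 (1.76 ± 0.39) and the cytochrome Cyp1a1 (1.39 ± 0.19), a target of the aryl hydrocarbon receptor. Falls were led by Fam107a (−1.62 ± 0.40), the transcription factors Klf15 (2.00-fold lower, SE 0.16 log2) and Max (−0.96 ± 0.14), the clathrin adaptor Ap2b1 (−0.96 ± 0.22), Hsph1, Lmcd1 (−0.78 ± 0.14), Syde2 (−0.74 ± 0.12) and Elmo1 (−0.74 ± 0.18). Without non-pregnant TiO2 replicates 1, 2, 3 and 4 the count was 52, 97, 57 and 113, without pregnant TiO2 replicates 1, 3 and 4 it was 69, 119 and 69, and without non-pregnant PBS replicate 3 it was 387. It was 21 with values as deposited (14 higher and 7 lower), 52 with Glycam1 as a covariate, where Marco no longer passed, and 1, Nr4a1, with the 3 tissue list means as covariates.

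The remaining lists called for pregnancy after TiO2 lost their call with an estimated correlation. Acute-phase (median 0.46, 3 of 14 passing), complement (0.40, 6 of 21), ciliated cell (0.29, 1 of 21) and immediate-early genes (0.23, 3 of 16) were higher, with adjusted p of 0.000309, 0.000830, 4.51e-05 and 0.00576, and adjusted p = 0.0908, 0.0709, 0.168 and 0.295 with an estimated correlation. Among them Nr4a1 (1.26 ± 0.17), the secreted matrix protein Ccn1 (1.04 ± 0.16), Pigr (0.64 ± 0.14), Procr (0.43 ± 0.07) and Cfap126 (0.64 ± 0.14) passed over all genes. T-cell (0.43), cell-cycle (0.26), NF-kB (0.20), alternative activation (0.23) and interferon-response genes (0.14) were higher with adjusted p of 0.00581, 0.00917, 0.0102, 0.0236 and 0.0486, and adjusted p = 0.557, 0.601, 0.168, 0.0888 and 0.557 with an estimated correlation. Glucocorticoid-response genes (−0.37) were lower with adjusted p = 0.000176 (adjusted p = 0.398 with an estimated correlation), with Klf15 and Klf9 (−0.33 ± 0.08) called, and matrix genes (−0.08) with adjusted p = 0.0380 (adjusted p = 0.528). Of the genes called higher by pregnancy, 35 were shared between the PBS and the TiO2 comparison where independent lists would share 1.37, and of those called lower 2 where they would share 0.148. These comparisons have no array in common, but they share the spread estimate of each gene, which favours the same genes in both. The numbers for independent lists are therefore too low a yardstick. Across genes the pregnancy effects after PBS and after TiO2 correlated with Pearson's r of 0.25 and Spearman's rho of 0.19.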

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

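All tests in this part except the splits of arrays and the test of the difference in TiO2 response were chosen after the result was seen; for those with tissue list means as covariates and with thymic genes below the filter, the bounds were written before their own values were seen. One rule picked a sample standing far from the other 3 of its group by Dixon's ratio of gap to range, which chance meets in about 1 in 20 groups. It was met 37 times in 836 groups of values (9 of 132 of list means, 28 of 696 of gene values and 0 of 8 of array brightness and mean level), where chance gives 41.8. Pregnant TiO2 replicate 2 holds 7 of them, non-pregnant TiO2 replicate 1 and pregnant PBS replicate 3 hold 5 each and pregnant PBS replicate 4 holds 4.

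Among list means, pregnant TiO2 replicate 2 stood far from its group in fat markers (7.99 log2, others from 9.76), striated muscle (8.47, others from 10.1), club cells (10.3, others from 10.8) and the hormone receptor list (8.43, others from 8.53). Acute-phase genes stood apart in pregnant PBS replicate 2 (9.24) and pregnant TiO2 replicate 4 (9.73), angiogenesis genes in non-pregnant TiO2 replicate 2 (9.43), endothelial genes in replicate 4 (10.87) and NF-kB targets in replicate 1 (8.76). Single genes of pregnant TiO2 arrays standing apart were Adipoq (8.65), Fabp4 (10.62) and Cnn1 (9.14) in replicate 2, Mzb1 (8.12) in replicate 1 and Pdgfrb (10.64) in replicate 4. In pregnant PBS arrays they were Apol11b (5.49), Gabrp (8.49), Lcn2 (10.95), Thrsp (10.02) and Trim10 (5.29) in replicate 3, and Ccnb2 (7.17), Klf15 (9.27), Saa3 (7.53) and Sncb (5.83) in replicate 4. In non-pregnant TiO2 arrays they were Chil3 (11.15), Hspa8 (13.01), Mzb1 (6.61) and Thy1 (7.39) in replicate 1, Marco (4.77) and Rsad2 (8.13) in replicate 2, Muc5b (7.41) and Syde2 (9.27) in replicate 3 and Pglyrp1 (7.45) in replicate 4. In non-pregnant PBS arrays they were Dnajb1 (9.33) in replicate 1, Mmp8 (7.06), Npnt (12.54) and Tubb1 (6.67) in replicate 2 and Errfi1 (10.3) in replicate 3.

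Camera at the preset correlation called the response to TiO2 different between pregnant and non-pregnant mice, by the test of the difference itself, for fat (median 1.06), thymocyte (0.98), T-cell (0.90), cell-cycle (0.72), B and plasma cell (0.44), neutrophil (−0.20), glucocorticoid-response (−0.30) and heat-shock genes (−0.11). None kept this call, with adjusted p = 0.650 to 0.780 with an estimated correlation. Splits of the arrays that mix the groups do not exclude chance for these 8 lists: 36 of 100 splits gave at least as many, and the highest other gave 18. In non-pregnant mice, 4 of 35 splits gave at least the 13 lists called after TiO2 (highest other 13), so chance is not excluded. In pregnant mice it is not excluded either, with 8 of 35 for the 9 lists (highest other 16). Where 0 genes were called, the splits decide nothing, since each gives at least 0 (35 of 35, 35 of 35 and 100 of 100 for TiO2 in non-pregnant mice, in pregnant mice and the interaction, with highest others of 2, 0 and 3). For pregnancy only the real split of 35 gave as many calls, which is the smallest share that 35 splits allow. It gave 129 genes after PBS and 233 after TiO2, where the highest other gave 2 in each case. For lists the margin was small, with 19 after PBS (highest other 17) and 18 after TiO2 (highest other 16). The gene counts thus stood far above those of the other splits, and the list counts only slightly above. No allowance was made for the number of results tested this way. Probe sets without a single gene symbol, outside the genes tested, were called in 14 of 2747 cases for pregnancy after PBS and in 14 after TiO2.

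Squamous and striated muscle genes were on all arrays but pregnant TiO2 replicate 2, where Krt4 was 5.41 against 12.0 to 12.7 and Myh1 5.09 against 10.8 to 12.0. A piece of oesophagus or another neighbouring tissue could bring both; the lists correlated with r = 0.758 over the other 15 arrays (permutation p = 0.00582), but with 0.0429 without the 2 farthest, so this cannot be told. The requirement that r hold without these 2 was added after r had been seen, and it turned the label away from this explanation. For a failed array, the alveolar type 2 list of pregnant TiO2 replicate 2 lay 0.0536 from the mean of the others. These genes average 11.7 log2, among the strong signals that quantile normalization holds close, so this list alone cannot exclude a failure. Before normalization the trimmed mean signal of this array was 261, within the 137 to 264 of all arrays. Its club cell list was lower, at 10.3 against 10.8 or more in the rest of its group. An effect of TiO2 in pregnant mice is excluded, since the other 3 pregnant TiO2 arrays lay 0.127 above the other 12 in the squamous list.

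Thymocyte, T-cell and cell-cycle genes were high in non-pregnant PBS replicates 3 and 4. Thymus tissue in these samples fits. Of 9 thymic genes below the expression filter, which entered no list mean, 8 were higher in both than on any other array. The median margin over the 9 was 1.62 log2. Foxn1 was the exception, at 5.06 and 5.55 against at most 5.48. The filter asks for at least 4 arrays, so genes high in only 2 fall below it. Taking genes below it therefore favours this pattern. Rag1, which recombines antigen receptor genes, was 9.16 and 9.66 against at most 5.05, and the thymic chemokine Ccl25 8.12 and 9.15 against at most 5.85. Lymph node tissue beside it stays open: the B-cell list was 8.20 and 7.82, against 7.65 and 7.96 in the other 2 of the group, so the lower one was at −0.142 relative to the higher of these and replicate 3 was above both. No biological explanation was tested.

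Neutrophil and platelet genes were higher in pregnant mice after PBS, and more blood left in their lungs could raise both. Haemoglobin and reticulocyte transcripts had a median change of 0.304 over 4 genes, 3 of them below the neutrophil median by more than 2 SE, so this cannot be told. For the neutrophil list, array brightness is excluded, since its median relative to all genes was 0.666 with values as deposited. Unequal thymus, fat and squamous tissue is excluded for that list too, whose plain median was 0.638 with these list means as covariates; platelet genes were not tested for either, and their median with the covariates was 0.701. Pregnancy itself is the biological explanation the design gives, and in the splits above no other grouping of the arrays gave as many calls. The 18S signal also differed between these groups after PBS, at 113 to 236 in non-pregnant and 65.4 to 101 in pregnant mice. The splits cannot tell such a difference from pregnancy.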

How the results depend on the processing

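Trimmed-mean scaling, fits without the 2 thymus arrays or the 3 arrays of unlike tissue content, and tissue covariates or Glycam1 as a covariate are tests chosen after the result was seen; all other alternatives were fixed earlier. No count, list mean or correlation reversed, nor did any of 70 named called results. Of these 70, only 19 stayed called with tissue covariates, 25 with the conflicting array counted as pregnant PBS and 29 with values as deposited. In each other setting where they were refitted, 47 or more stayed called. Medians of some called lists, however, changed sign under values as deposited, trimmed-mean scaling, left-out arrays or covariates. Only the T-cell list was then called the other way, by camera at the preset correlation. For pregnancy after PBS it went from −0.44 to 0.30 without the 2 arrays. With tissue covariates it went to 0.36 there, to 0.23 for TiO2 in non-pregnant mice and to −0.26 for the interaction. Genes changed by TiO2 in non-pregnant mice (0) numbered 1 without the filter (Atp4a), and those in pregnant mice (0) 1 with array weights (Trem3), 1 with values as deposited (Nppa) and 2 without the 2 thymus arrays (Birc5 and Trem3). For the interaction (0) there were 1 without the filter (Atp4a) and 4 without the 3 arrays (Lysmd1, Sfrp4, Tab3 and Telo2). Genes changed by pregnancy after PBS (129) numbered 214 at adjusted p under 0.10, 49 with the compared arrays only and 38 as deposited. They numbered 7 with the conflicting array counted as pregnant, 245 without 2 arrays, 294 without 3 and 132 with tissue covariates. They included 90 of the 129 without 2 arrays, 96 without 3 and only 60 with tissue covariates. After TiO2 (233) they numbered 735 at 0.10, 1505 with array weights, 483 with the compared arrays only, 141 without the filter, 104 with the conflicting array as pregnant, 21 as deposited, 426 without 2 arrays, 450 without 3, 1 with tissue covariates and 52 with Glycam1 as a covariate. With an estimated correlation the lists called were 0, 0, 0, 3 and 5 for TiO2 in non-pregnant mice (13), in pregnant mice (9), the interaction (8), pregnancy after PBS (19) and after TiO2 (18), and with fry 1, 2, 0, 8 and 12; estimated without the 3 arrays they were 0, 0, 0, 2 and 1. Without the 2 arrays the lists were 6 for TiO2 in non-pregnant mice, 4 for the interaction and 11 for pregnancy after PBS. Of these, 5, 2 and 11 were among the lists called with all arrays. Without the 3 arrays they were 6, 8 and 11, of which 5, 3 and 11 were among those lists. With covariates they were 5 for TiO2 in non-pregnant mice and 11 for pregnancy after PBS. With Glycam1 as a covariate the lists for TiO2 in non-pregnant mice were 8 and the correlation of TiO2 effects −0.22. The cytokine mean in pregnant mice went to 0.11 (exact p = 0.0286) without the filter, where more genes enter the list. The neutrophil mean there went to −0.28 (exact p = 0.143) with the conflicting array as pregnant and to −0.37 (exact p = 0.0571) without the 3 arrays. With each array left out in turn the gene counts ranged over 0 to 5, 0 to 1, 0 to 2, 72 to 217 and 52 to 387 in the order above, and the list counts over 7 to 14, 7 to 12, 6 to 9, 14 to 19 and 14 to 20. The cytokine means ranged from −0.06 to −0.01 and 0.05 to 0.09, the neutrophil means from −0.18 to −0.09 and −0.47 to −0.35, in non-pregnant and pregnant mice, and the correlation of TiO2 effects from −0.14 to −0.01. Otherwise the cause was not tested. No paired analysis was possible because the labels carry no replicate number shared between groups; the numbers used here only follow the order of the samples. Signals near the floor, such as Marco or Il6, limit what can be seen of weak genes.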

Other observations

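Camera called no directional shift of 6 lists in any comparison, though single members passed over all genes for pregnancy: 1 angiogenesis gene lower after PBS, and 1 angiogenesis gene and 1 of the Nrf2 list higher after TiO2. Alveolar type 2 and surfactant genes (20 measured) had medians between −0.05 and 0.06 log2 in the 5 comparisons, angiogenesis and hypoxia genes (25) between −0.04 and 0.03, circadian clock genes (15) between −0.11 and 0.10, and hormone receptor genes (12) between −0.13 and 0.10. Genes of MHC class II and dendritic cells (16) lay between −0.05 and 0.11, and those of the Nrf2, antioxidant and metal response (24), which includes Hmox1, between −0.01 and 0.06, with a lowest camera adjusted p of 0.0892. The uncoupling protein Ucp1 of brown fat ranged from 4.15 to 10.5 log2 over the 16 arrays. Marco was at 6.02 to 6.40 in all 8 pregnant mice and at 4.13 to 6.55 in the non-pregnant ones.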
